A study of Arabidopsis thaliana with 35 samples.

How the data were processed

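Transcripts were measured by RNA-seq of poly(A) RNA from 7-day-old whole seedlings of the C24 wild type (2 libraries) and the acx4 mutant (2 libraries). The submitters' processing notes name TopHat2 version 2.1.1, Cuffdiff version 2.1.1 and the TAIR10 genome build, without saying which step each was used for. The authors deposited 4 tables of their own comparison of acx4 with wild type, for genes that fell, genes that rose, TEs that fell and TEs that rose. Each table gives a log2 fold change, which the authors computed as acx4 over wild type, and the authors' P value, which the tables do not assign to a tool or describe as adjusted or unadjusted. Per the file headers, genes were kept at a change of at least 2-fold and P under 0.05 and TEs at a change of at least 2-fold and P under 0.005, and every deposited value was checked to lie within these limits. No column held a value per library, no fold change was infinite, and no expression level was given, so the depth per sample is unknown and no interval that needs counts is given. The 7 bisulfite libraries, 14 chromatin immunoprecipitations and 10 inputs were not analysed here.

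Groups were taken from the sample labels. The gene identifiers were matched to a reference table of assembly TAIR10.1, which is named differently from the build of the submitters' notes and was therefore used only for symbols, gene types and the order of neighbouring genes. All 1427 genes matched, 37 of them listed with a suffix that was removed for the match. Chromosomes were read from the identifiers, and no coordinates are given. Descriptions (1188 genes), GO terms (1356 genes) and pathways (190 genes) came from the deposited tables.

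The tests, the gene lists, the family patterns, the rule for named genes and the main alternatives were fixed before the data were examined. There were 19 lists with 391 gene codes, of which 378 matched their symbol in the reference, 13 had no symbol there and 0 were dropped, and 18 families defined by words of the annotation. Because the tables hold changed genes only, enrichment was not tested: each list or family with at least 5 changed members was compared in direction with all other changed genes by a two-sided Fisher exact test, with Benjamini-Hochberg adjustment over lists or over families. Shares were tested by exact binomial tests with Clopper-Pearson intervals. The size of change, the direction of neighbours and the direction by chromosome were tested by 100000 permutations among changed genes. The planned limma fit of values per library could not be run on these tables. Family words were matched at the start of a word after a first look had shown matches inside other words, such as ERF in superfamily; the patterns as first written were run as an added alternative. GO terms with at least 10 and pathways with at least 5 changed genes were tested in the same way, as an addition made after the data were seen.

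Named genes were ACX4, the 10 genes with the largest absolute log2 fold change in each direction, the 5 such TEs in each direction and up to 4 changed members per list or family by the same ranking. The rule's minimum expression level could not be applied without levels. The 10 genes with the smallest P in each direction and members of neighbouring runs were added after the data were seen. So were the DNA-methylation genes VIM5 and CMT1, and SDC, a gene kept silent by DNA methylation. Single members whose direction or identity differed from their group, or that the family words missed, were also added then. For each list, the number of members that pass a Benjamini-Hochberg adjustment over the list alone was counted with unlisted members at P of 1, beside the number sure to pass over all genes if P was unadjusted and all 38312 genes of the reference table were tested; the largest P that passed the second was 9.60e-04.

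The steps were tested on simulated data for the list of 1427 genes. Lists of 11 or 20 genes that all fell were called in 100% of simulations, lists of 6 that all fell in 0%, and lists without a direction of their own in 2.5% to 4.2%. In 100 simulations each, the tests of neighbours, size and chromosome called 100% of simulated effects and 2%, 4% and 8% of null data. Alternatives were P of at most 0.01 or 0.001, an absolute log2 fold change of at least 2, tandem neighbours of a list counted once, the Benjamini-Hochberg bound, leaving out genes of large change at weak P, other family patterns and other definitions of neighbours. Not run were alternatives that need expression levels, pseudocounts, another normalization or values per library, and those that need distances in bases, including the planned test of changed genes near changed TEs. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.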

Results

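The series covered DNA methylation, histone acetylation and transcript levels in Arabidopsis thaliana seedlings, in wild types, in lines mutated in steps of peroxisomal beta-oxidation and in ros1-4, a mutant of a DNA demethylase. Of its 35 samples, 4 were RNA-seq libraries, 7 were bisulfite libraries, 14 were chromatin immunoprecipitations of acetylated histone H3 and 10 were their inputs. The bisulfite and chromatin samples were not analysed here. RNA was taken from 7-day-old whole seedlings grown on plates with sucrose, with 2 libraries of the C24 wild type and 2 of the acx4 mutant. ACX4 encodes a peroxisomal acyl-CoA oxidase that starts the breakdown of short-chain fatty acids, a route that releases acetyl-CoA. The question put to these libraries was which genes and transposable elements (TEs) change their transcript level when this enzyme is lost. The data used were the authors' own lists of changed genes and TEs, each with a log2 fold change of acx4 over wild type and a P value. They held no value per library and no level, so no standard deviation can be given, the depth is unknown and a gene outside the lists cannot be told from one that was not measured. The labels do not say whether the 2 libraries of a group came from separate cultures, so any spread between them may be technical. The P values are assigned to no tool, so whether they take in the spread between libraries at all is unknown.

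ACX4 itself (AT3G51840) fell 5.29-fold in the mutant, with a log2 fold change of -2.40 and P = 2.49e-11 in the authors' deposited table. The authors' deposited tables listed 1427 genes, of which 916 fell and 511 rose. Genes that fell made up 64.2% of the list, with an exact Clopper-Pearson 95% interval of 61.6% to 66.7% (exact two-sided binomial test against equal shares, p = 4.89e-27; genes are not independent, so this describes the list). Among genes that changed at least 4-fold, 337 fell and 190 rose. The median absolute log2 fold change was 1.68 for genes that fell and 1.58 for genes that rose, a difference that a two-sided permutation test did not separate from 0 (p = 0.115, 100000 permutations). The authors' lists required a 2-fold change at P under 0.05, and neither the lists nor the notes say whether P was adjusted. The count moved to 745 genes at P of at most 0.001 and to 742 genes that are sure to pass a Benjamini-Hochberg adjustment if P was unadjusted and no more than the 38312 genes of the reference table were tested, a lower bound.

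**Figure D1:**
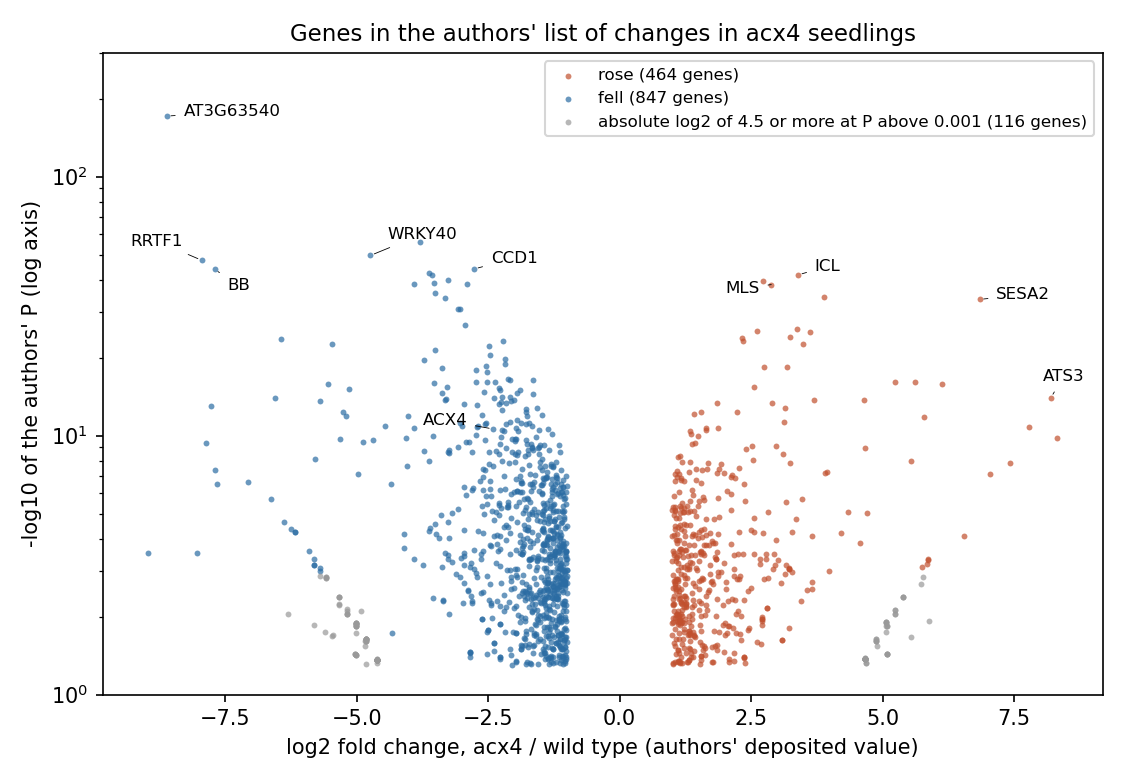
Each point is a gene of the authors' deposited tables, with the log2 fold change of acx4 over wild type on the horizontal axis and -log10 of the authors' P on a vertical log axis. Genes that rose are orange, genes that fell are blue, and 116 genes with an absolute log2 fold change of at least 4.5 at P above 0.001 are grey; AT3G63540, at -8.61, has the smallest P.

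Among the 10 deepest falls were 3 transcription factors and 2 neighbouring genes at the end of chromosome 3. RRTF1 (AT4G34410), a redox-responsive factor of the AP2/ERF family, fell to a log2 fold change of -7.95 in the authors' deposited table, CBF4 (AT5G51990), a drought-responsive C-repeat-binding factor, to -7.88, and DDF1 (AT1G12610), a related factor, to -7.78. AT3G63540, annotated as a PsbP family protein, fell to -8.61 in the authors' deposited table, and BB (AT3G63530, BIG BROTHER), a ubiquitin ligase that limits organ size, to -7.70. The smallest P of the authors' deposited table, 6.30e-172, belonged to AT3G63540. The other 5 of the 10 deepest falls in the authors' deposited table were AT1G58684, the deepest of all (-8.97), AT5G36710 (-8.04), the noncoding RNA AT2G06002 (-7.70), MLP31 (-7.66) and the pseudogene AT1G56490 (-7.07). AT1G58684 is uncertain, because it encodes a ribosomal protein with a near-identical copy, AT1G59359, which the authors' deposited table listed at 2.56 in the other direction. Falls with the smallest P, a second ranking chosen after the values were seen, added the dicarboxylate carrier DIC2 (-3.79), WRKY40 (-4.74), the carotenoid cleavage dioxygenase CCD1 (AT3G63520, -2.77), the potassium transporter HAK5 (-3.63), the deadenylase CAF1a (-3.56), the ethylene synthesis gene ACS6 (-3.27) and AT1G07135 (-3.54), all from the authors' deposited table.

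The 10 largest rises included 3 seed genes and a fatty acid elongase. The seed gene ATS3 (AT5G07190) rose to a log2 fold change of 8.20 in the authors' deposited table, the seed storage albumins SESA2 (AT4G27150) and SESA4 (AT4G27170) to 6.85 and 6.13, and KCS18 (AT4G34520, FAE1), which elongates fatty acids in seeds, to 7.04. The largest rise in the authors' deposited table, 8.32, belonged to AT1G47540, a knottin-type protein. CYP96A3 (7.78), the glucosinolate side-chain gene AOP3 (7.42), the pseudogene AT3G21040 (6.55), AT4G18450 (5.89) and AT1G28327 (5.86) completed the 10 largest rises of the authors' deposited table. Ranked by P, again after the values were seen, the rises were led by ICL (AT3G21720, isocitrate lyase) at 3.39, LTP2 at 2.74 and MLS (AT5G03860, malate synthase) at 2.88 in the authors' deposited table. In order of P, the next were AT3G28500 at 3.89, SESA2, the plastid glucose-phosphate translocator GPT2 at 3.38, AT1G80130 at 2.62, ELIP1, a light-stress protein of chloroplasts, at 3.61, AT2G47780 at 3.24 and AT5G44440 at 2.33 in the authors' deposited table.

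Every member of the list of early wound, touch and elicitor genes fell. All 20 of 20 members were in the authors' deposited table of falls, with a median log2 fold change of -2.73. Besides RRTF1, the deepest were the calmodulin-like genes CML38 (-5.27) and CML37 (-4.46) and the transcription factor WRKY40 (-4.74) in the authors' deposited table. The jasmonate list moved the same way, with 11 of 30 members listed and all 11 lower. In the authors' deposited table they included the lipoxygenases LOX4 (-3.91) and LOX3 (-2.29) and the jasmonate repressors JAZ5 (-3.63) and JAZ7 (-2.93). Against all other changed genes, the share that rose was lower in the wound list (0 of 20, adjusted p = 7.69e-04) and in the jasmonate list (0 of 11, adjusted p = 0.0157) by two-sided Fisher exact tests with Benjamini-Hochberg adjustment over 8 lists. With only genes of an absolute log2 fold change of at least 2, a setting added after the data were seen, 6 jasmonate genes were left, all 6 of them lower, and the exact test gave an adjusted p of 0.0922. No fall among 6 genes could pass this test, since all 6 lower is the most extreme case. Adjusted over the list alone, 20 of the wound genes and 11 of the jasmonate genes passed, against 18 and 10 adjusted over all genes. Both counts take P as unadjusted. The 20 wound genes were bound to pass over their list, since every member was listed at P under 0.05. Genes are not independent, so the Fisher tests of direction for lists, families and GO terms describe only the genes listed. Those tests do not measure how the changes would repeat in other seedlings.

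Most cold and salicylate genes were not listed, and the directions of those listed did not pass the test. All 6 listed members of the 23 cold, drought and abscisic acid genes fell, led in the authors' deposited table by the cold-response factors CBF2 (-5.70), CBF1 (-4.88) and CBF3 (-2.01) and by DREB2A (-1.94). The exact test gave an adjusted p of 0.108, and 6 falls could not have reached the threshold in simulated lists of that size. CBF1, CBF2 and CBF3 are similar genes, so reads could be split between them and their separate values are uncertain. Of 21 salicylate and defence genes, 7 fell and 1 rose (Fisher exact test, adjusted p = 0.272). The authors' deposited table gave -2.96 for PCC1, -2.94 for WRKY70, -2.44 for WRKY54 and -2.08 for CBP60G, and CYP71A13, a camalexin synthesis gene, was the member that rose (1.88). Adjusted over the list alone, 6 cold genes and 7 salicylate genes passed, against 6 and 6 over all genes.

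The seed storage genes that were listed all rose. Of 19 seed storage and maturation genes, 9 were listed and all 9 rose, with a median log2 fold change of 4.21 in the authors' deposited table. SESA2 and SESA4 were followed by SESA1 (5.54) and the cruciferin CRU2 (4.70) in the authors' deposited table. The 4 SESA genes are similar neighbours, so reads could be split between them. The other 10 were not listed, among them the albumin gene SESA5, the oleosin genes OLEO1 and OLEO2, EM1, EM6 and the regulators LEC1, FUS3 and ABI3. Of 23 genes of iron deficiency and storage, 10 were listed, 8 as higher and 2 as lower; the other 13, IRT1, FRO2 and FIT among them, were not listed. The transcription factors BHLH101 (2.75), BHLH100 (2.29) and BHLH38 (2.26) and the peptide gene IMA2 (2.12) had the highest values in the authors' deposited table, while those that fell were the iron-storage ferritins FER1 (-1.23) and FER4 (-1.08). Of 18 flavonoid and anthocyanin genes, 12 were not listed, CHS and CHI among them, and the 6 listed all rose, including the regulators PAP1 (2.35) and PAP2 (2.31), the transport gene TT19 (1.90) and the acyltransferase 5MAT (1.45) in the authors' deposited table. The direction differed from that of other changed genes for the seed list (9 of 9 rose, adjusted p = 7.40e-04), the iron list (8 of 10, adjusted p = 0.0110) and the flavonoid list (6 of 6, adjusted p = 0.00552; Fisher exact tests). Adjusted over the list alone, 9 seed, 10 iron and 5 flavonoid genes passed, against 8, 8 and 5 over all genes.

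**Figure D2:**
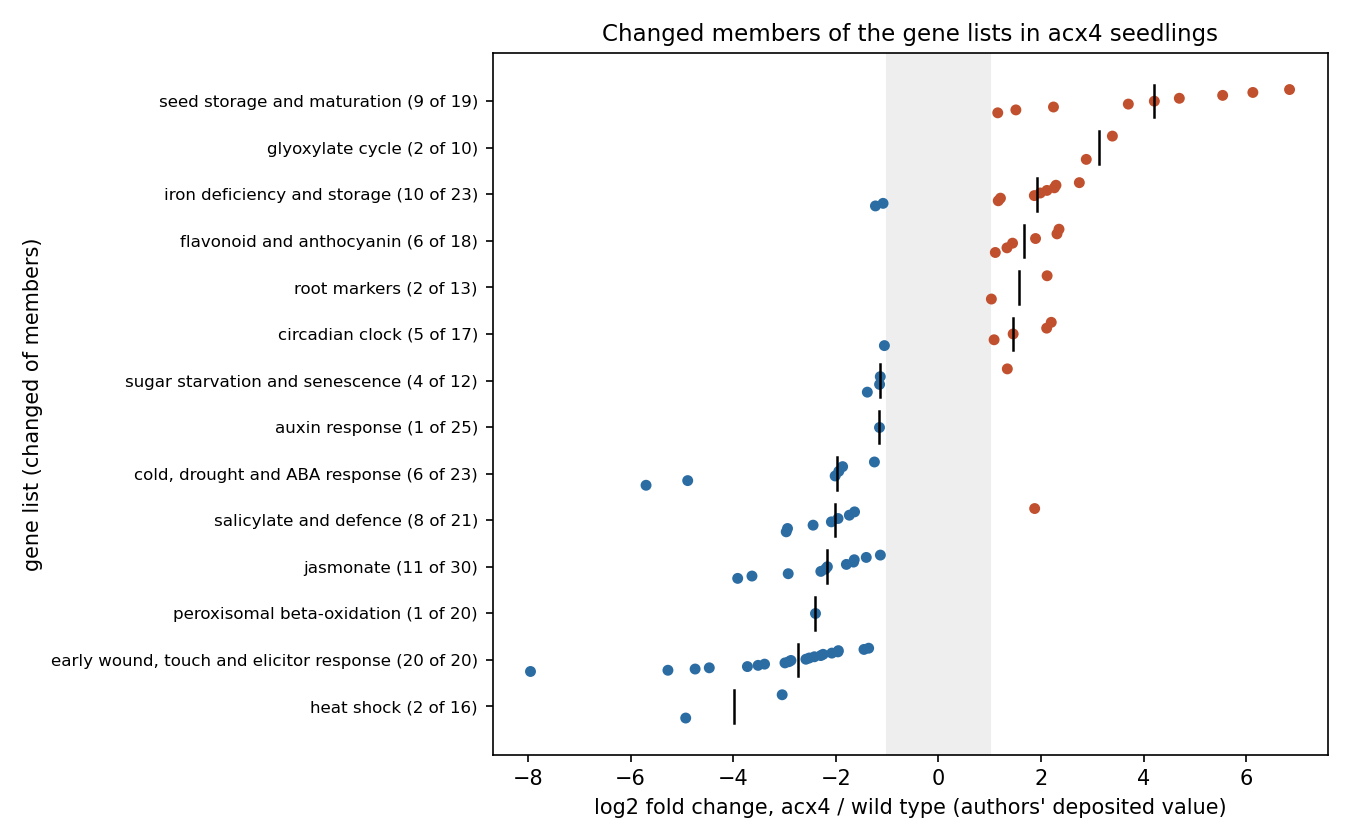
Each point is a changed member of a gene list, placed by its log2 fold change of acx4 over wild type in the authors' deposited table; black bars are medians, numbers are changed members of all members, and the grey band marks changes under 2-fold, which the lists leave out. All 20 wound, touch and elicitor genes lie to the left and all 9 seed storage genes to the right.

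Among clock genes, the morning genes RVE8 (2.201), CCA1 (2.11), RVE1 (1.46) and LHY (1.09) rose and BOA (-1.05) fell in the authors' deposited table, 4 of 5 listed members of 17 (Fisher exact test, adjusted p = 0.0778). Adjusted over the list alone 5 clock genes passed, against 3 over all genes. The other lists had fewer than 5 changed members and were not tested for direction. In the glyoxylate cycle, which uses acetyl-CoA, ICL and MLS rose and the other 8 of 10 members were not listed. Of 20 genes of peroxisomal beta-oxidation, ACX4 alone was listed. Both small heat shock genes listed among 16 fell, HSP17.6A (-4.92) and HSP17.4 (-3.04), and both listed root markers among 13 rose, CASP5 (2.12) and PRP3 (1.03), according to the authors' deposited table. Of 12 sugar starvation and senescence genes, DIN10 (-1.38), SEN1 (-1.14) and PRODH1 (-1.13) fell and DIN2 (1.34) rose in the authors' deposited table. IAA6 (-1.16) was the one auxin-response gene of 25 in the authors' deposited table. Adjusted over the list alone, 2 glyoxylate, 1 beta-oxidation, 1 heat shock, 2 root marker, 3 starvation and 0 auxin genes passed, against 2, 1, 0, 2, 2 and 0 over all genes.

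No member of the fixed lists for DNA methylation and histone acetylation was listed. None of 35 genes of DNA methylation and demethylation, ROS1 included, and none of 28 histone acetyltransferases and deacetylases was in the authors' deposited tables. These lists do not cover every such gene: VIM5 (AT1G57800), of a family that maintains DNA methylation, rose (2.14, P = 9.53e-08) and the chromomethylase CMT1 fell (-2.64) in the authors' deposited table, both picked out after the values were seen. The same zero count held for 26 nuclear photosynthesis genes, 20 glucosinolate genes and 15 oxidative stress genes, lists that are not complete either: AOP3, named above, is a glucosinolate gene outside its list. Absence from the lists means a change under 2-fold, a P of at least 0.05 or a gene that was not measured, and these cannot be told apart here.

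Receptor-like kinase and resistance genes that changed were mostly lower; members that were not listed are unknown. All 29 changed genes described as receptor-like kinases fell, among them AT5G41290 (-3.36), AT1G07550 (-3.27), AT1G61750 (-2.96) and CRK10 (-2.28) in the authors' deposited table. The family was matched by annotation words, which also took in TIR, a receptor-like protein that is not a kinase, and missed PERK12, a receptor kinase that rose (1.17) in the authors' deposited table. Genes matched by the words for disease resistance of the NBS-LRR type, a class of intracellular immune receptors, fell in 21 of 23 cases. They included WRR4 (-4.05), AT1G66090 (-3.52) and AT3G04210 (-2.54), although AT4G11340 (5.07) rose in the authors' deposited table. Whether each match is a full receptor of this type was not checked. Defensin and thionin genes rose in 6 of 7 cases, with AT5G33355 (5.24), AT1G13609 (2.93) and AT1G13608 (2.17) higher and AT3G63360 (-5.33) lower in the authors' deposited table. Fisher exact tests of direction, adjusted over 13 families, gave adjusted p = 5.06e-05 for receptor-like kinases (0 of 29 rose), 0.0436 for NBS-LRR genes (2 of 23 rose) and 0.0436 for defensins and thionins (6 of 7 rose). Neighbouring genes were counted separately in the families, and no setting counted them once. AT1G13608 and AT1G13609 are neighbours, so the 6 rises of defensins and thionins are not independent. At P of at most 0.01 the NBS-LRR and defensin families missed the threshold (exact tests, adjusted p = 0.0655 and 0.1001). Fewer members were left there, and 5.88% of 17 NBS-LRR genes and 80% of 5 defensin and thionin genes rose. The receptor-like kinases missed it at an absolute log2 fold change of at least 2 (5 genes, 0% rose, exact test, adjusted p = 0.330). No fall among 5 genes could pass there, since all 5 lower is the most extreme case.

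None of the other 10 families tested passed the test of direction with the lists as deposited. F-box genes passed only once genes of large change at weak P were left out, a setting added later (77.8% of 9 rose, exact test, adjusted p = 0.0381). WRKY factors fell in 9 of 11 cases, with WRKY55 (-5.34), WRKY70 (-2.94) and WRKY33 (-2.91) beside WRKY40 in the authors' deposited table (Fisher exact test, adjusted p = 0.670). Genes matched by the words for AP2/ERF factors fell in 8 of 9 cases, including ERF11 (-3.39), ERF5 (-2.99), ERF6 (-2.58) and ERF13 (-2.34) in the authors' deposited table (Fisher exact test, adjusted p = 0.466). These words missed RRTF1, CBF4 and DDF1, which fell further; with genes described as Integrase-type counted, an alternative added later, 19.2% of 26 genes rose (Fisher exact test, adjusted p = 0.317). Cytochrome P450 genes were split into 9 that rose and 24 that fell, SAUR genes into 4 and 7 (80% of 5 rose at P of at most 0.01), F-box genes into 8 and 7 (83.3% of 6 rose at that limit), MYB factors into 2 and 7, peroxidases into 4 and 6, UDP-glycosyltransferases into 3 and 7, expansins and xyloglucan enzymes into 2 and 4, and glutathione S-transferases into 2 and 3. Ribosomal protein (4), histone (3), heat shock protein (2) and TE-described genes (1) were too few to test, and the words for chlorophyll-binding proteins matched none, although they missed ELIP1 and ELIP2, described as chlorophyll A-B binding proteins, which rose (3.61 and 1.85 in the authors' deposited table). Among the genes named, WRKY55, AT4G11340, AT5G33355, AT3G63360, AT4G18450 and HSP17.6A belong to 116 genes with an absolute log2 fold change of at least 4.5 at P above 0.001, most of which share their exact value with another gene (87 of 116, to within 0.0001).

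TEs were listed in both directions in similar numbers. The authors' deposited tables listed 70 TEs, of which 37 fell and 33 rose, at a 2-fold change and P under 0.005. The share that fell, 52.9%, had an exact Clopper-Pearson 95% interval of 40.6% to 64.9% (exact two-sided binomial test, p = 0.720). The share that fell in TEs against genes, compared by a two-sided Fisher exact test, did not pass the threshold with the lists as deposited, which differ in their P limit (odds ratio 0.625, p = 0.0571). Both were also held to the same P of at most 0.001, a setting added after the data were seen. There a smaller share of TEs than of genes fell (Fisher exact test, odds ratio 0.524, p = 0.0396). P of at most 0.01 cut the genes only, since all 70 TEs met it (Fisher exact test, p = 0.0264). With an absolute log2 fold change of at least 2, also added, and the P limits as deposited, the Fisher exact test gave p = 0.407. The largest falls were AT5TE80015 (-6.31), AT4TE39200 (-5.80), AT5TE65335 (-5.33), AT5TE39170 (-5.32) and AT1TE99345 (-5.11) in the authors' deposited table. The largest rises in the authors' deposited table were AT3TE30975 (6.56), AT2TE15975 (6.21), AT4TE85890 (5.96), AT2TE16180 (5.75) and AT2TE33940 (5.39). AT3TE30975 has nearly the value of the pseudogene AT3G21040 (6.55) in the authors' deposited table. TE families were not used here.

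Changed genes that sat next to each other mostly moved together. Of 99 pairs of changed genes that are neighbours in the annotation, 80 had the same direction, or 80.8%, against 54.0% when directions were permuted among changed genes (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). The share was 78.4% over 88 pairs once neighbours with the same description were left out. That setting kept differently numbered relatives, such as SESA1 and SESA2, and neighbours without a description. It therefore cannot tell a direction shared by unrelated neighbours from one shared by related genes. There were 12 runs of at least 3 adjacent changed genes, and 11 of them had 1 direction. The baruol synthase gene BARS1 (-5.47) and its neighbours CYP705A4 (-1.98), AT4G15390 (-1.73), CYP702A5 (-3.19) and CYP702A6 (-1.72), a group of triterpene-type genes, all fell in the authors' deposited table. CCD1, BB and AT3G63540, the last 3 annotated genes of chromosome 3, also fell together. By chromosome, 61.7% to 66.6% of changed genes fell, and the 5 chromosomes did not differ past the threshold (permutation test, p = 0.565).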

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

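All settings here except P of at most 0.01, the counts of genes and TEs at P of at most 0.001 or an absolute log2 fold change of at least 2, and tandem neighbours counted once were added after the data were seen. The lean toward falls held in all settings run, at 63.9% to 68.3% of genes, as did the shared direction of neighbours, at 75.6% to 85.2% of pairs. Counts moved with the threshold by construction. At P of at most 0.001 there were 745 genes (236 rose, 509 fell), under the Benjamini-Hochberg bound 742 (235 rose, 507 fell), and at an absolute log2 fold change of at least 2 there were 527 genes (190 rose, 337 fell) and 42 TEs (18 rose, 24 fell). The wound and seed lists passed in all 7 settings and the iron and flavonoid lists in all 6 in which they had 5 changed genes. These counts include the lists as deposited. The other settings are parts of the same lists, and P of at most 0.001 and the Benjamini-Hochberg bound kept nearly the same genes, so the settings are not independent. At an absolute log2 fold change of at least 2, where 3 lists could be tested, 2 passed; the 6 jasmonate genes left all fell, too few for a fall to pass. The number of families past the threshold fell from 3 to 1 at P of at most 0.01, to 1 at P of at most 0.001, to 1 under the Benjamini-Hochberg bound and to 0 at an absolute log2 fold change of at least 2, where fewer members remained. With patterns matched anywhere in a word, the AP2/ERF family took in 261 genes, of which 41.4% rose, a reversed lean against other genes that came from matches in the word superfamily. F-box genes passed once genes of large change at weak P were left out (77.8% rose, adjusted p = 0.0381, between 0.0381 and 0.754 over its settings). The difference in median absolute log2 fold change, rose minus fell, was -0.179 at P of at most 0.001 (permutation p = 0.0378) and -0.182 under the bound (permutation p = 0.0339), both past the threshold, and 0.2004 with the sign reversed at an absolute log2 fold change of at least 2 (permutation p = 0.293); the cause was not tested. No paired analysis was possible because the tables hold no values per library, and leaving out a replicate could not be done for the same reason. A minimum absolute log2 fold change of 1 is the authors' own threshold and moved nothing.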

Other observations

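The tests in this part were chosen after the results were seen. Among 19 GO terms of the authors' deposited tables, 4 passed the test of direction. Each gene was counted under at most 1 term, so changed genes that also carry one of these terms may be left out. All 24 changed genes counted under the response to chitin were lower (Fisher exact test, adjusted p = 6.99e-04). They included AT5G51190 (-3.51), the ubiquitin ligase CMPG1 (-1.99) and NAC062 (-1.69) in the authors' deposited table. Of 26 genes counted under the innate immune response, 25 fell (exact test, adjusted p = 0.00232). Of 24 genes counted under kinase activity, 22 fell (exact test, adjusted p = 0.0197), among them the wall-associated kinase WAK1 (-1.45) in the authors' deposited table. Nutrient reservoir genes rose in 9 of 10 cases (exact test, adjusted p = 0.00399), with AT1G03890, a cupin, at 5.23 in the authors' deposited table. The defense response to fungus (12 of 14 fell, exact test, adjusted p = 0.375) and the defense response (7 of 10 fell, exact test, adjusted p = 1) did not pass. These terms share members with the lists and families above. None of 9 pathways passed; all 7 changed genes assigned to tetrahydrofolate biosynthesis II fell (exact test, adjusted p = 0.440).

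SDC (AT2G17690), an F-box gene kept silent by DNA methylation of its promoter, was listed as lower in the authors' deposited table (-1.31, P = 0.0127). This P is above 9.60e-04, the largest that passed the Benjamini-Hochberg bound over all genes. The level of SDC is unknown, so the fall may rest on few reads, and its cause was not tested. Of the changed TEs on chromosome 3, 13 rose and 3 fell, and direction differed between chromosomes over all 70 TEs (permutation test, p = 0.00821), and over 66 with adjacent TEs of 1 direction counted once (permutation test, p = 0.0390). Of those that rose, 4 are consecutive: AT3TE30960, AT3TE30965, AT3TE30970 and AT3TE30975. At 1.11, 1.12, 2.69 and 6.56 in the authors' deposited table, they have nearly the values of the consecutive pseudogenes AT3G21010, AT3G21020, AT3G21030 and AT3G21040, at 1.09, 1.1, 2.68 and 6.55. With these 4 TEs and 4 pseudogenes left out, since they prompted the test, 66 TEs and 33 other suffixed genes remained. Of these TEs, 13 lay within 0.05 of the log2 fold change of such a gene on their chromosome. The mean was 7.14 when TE values were permuted over all chromosomes (permutation test, p = 0.0118). Because direction differed between chromosomes, a direction shared within a chromosome could also raise the count. The test therefore cannot tell matching values from shared direction.

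The last 3 annotated genes of chromosome 3 fell, with log2 fold changes of -2.77 (CCD1), -7.70 (BB) and -8.61 (AT3G63540) in the authors' deposited table, more deeply toward the end, and the next gene inward, AT3G63510, was not listed. Placement of the values without regard to position rarely gave such a run. A mean this low over 3 adjacent changed genes came up in a share of 0.00055 of permutations of the values. The same 3 genes prompted this test, and changed neighbours mostly shared direction. It therefore cannot settle how unusual this run is. A change at all chromosome ends has no listed gene in its favour (0 of 27 genes at the other ends), but genes that were not measured would look the same, so it stays open. A lesion of this chromosome end in the mutant line, on the chromosome that carries ACX4, may explain a mean log2 fold change of -6.36; the expression values cannot tell a deletion from silencing or from a segment of another strain. No biological explanation was tested.

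All 20 early wound, touch and elicitor genes fell. Another time of day at harvest could not be tested: 4 of 4 dawn genes of the clock rose, but this set was put together after their values were seen, 3 other morning genes (LNK1, LNK2 and PRR9) were not listed, and of 8 evening genes 1 was listed (BOA, which fell). It stays open. A lack of jasmonate alone, which beta-oxidation helps to make, would not by itself lower salicylate genes; of those listed, 7 of 8 fell (exact two-sided binomial test against equal shares, p = 0.0703). That test decides nothing, because 64.2% of all listed genes fell and the salicylate list's direction did not pass against other changed genes (Fisher exact test, p = 0.272), so this stays open. A difference in touch or handling between the groups at harvest was not tested, and neither was the loss of ACX4 as such, since each group is 1 genotype with 2 libraries.

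Large fold changes came with weak P values in 116 genes (47 rose, 69 fell) with an absolute log2 fold change of at least 4.5 at P above 0.001, and 87 of them shared their value with another gene to within 0.0001, against 2 of the 55 other genes of that size. Over the 111 of these genes low enough for steps to be told apart, fold changes minus 1 lay within 0.1 step of a whole multiple of 1 step in 65 of 67 falls (step 3.93) and 39 of 44 rises (step 4.08), at a mean distance of 0.0271 steps against 0.217 for random folds. Many of these values are shared, so genes are not independent here; with each cluster of values (gaps of at most 0.03 in log2) counted once, 15 values gave 0.0521 steps against 0.163. In both tests random folds came as close in a share of 0.0001 of 10000 draws, the smallest that they can give. A few reads in one group against none in the other is a candidate explanation, with sizes that may depend on a constant added to low values; without these genes 64.6% of genes fell, and no biological explanation was tested.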
